A study of Mus musculus with 6 samples.

How the data were processed

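Expression was measured on 6 dual-colour arrays, each carrying RNA of LPS-treated and of untreated RAW 264.7 cells. The sources name the cell line as 264.7 in most places and as 264.4 in the series title and in part of the sample descriptions; 264.7 is used here. Per the labels, treated RNA was in Cy5 and untreated RNA in Cy3 on 3 arrays and the reverse on 3, and each orientation has sets 1, 2 and 3. The labels do not say whether a set number marks one pair of RNA extracts.

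The deposited values are log2 ratios of the 2 channels of one array, as read from their signs and range. Their background correction and normalization, and the scanner, are not given in the sources used here, and scanner intensities were not analysed here. Each deposited column has a median of 0, which was left as it is, so centring was done by the authors or follows from the exact zeros. The highest values equal the log2 of 100 (6.644), so ratios above 100 look capped, and the direction stays unstated. Exact zeros made up between 9.56% and 12.86% of the probes of an array. They were taken as probes with no ratio given, because 1074 probes were 0 on all 6 arrays and 1789 on some. Without them the column medians lay between -0.002 and 0.027.

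Of 16281 probes, 13738 named exactly 1 gene symbol in the platform annotation, 52 named several and 2491 were not listed and so are unnamed here. The gene table of assembly GRCm38.p6 held 13694 of the Entrez identifiers, and 0 symbols needed an update. This table was used for names and gene order only, and no coordinates are printed because the probes carry no genome build. Probes with a ratio on all 6 arrays (13418) were kept. A gene's value is the mean of its probes that name 1 symbol, which gave 9607 genes, 1846 with more than 1 probe. The probes of a gene spanned a median of 0.121 on the log2 scale, and 28 genes had probes called in opposite directions. Probe sequences were not analysed here, so members of families with near-identical copies (Slfn, Ifit, Ifi200, Gbp, H2, Bcl2a1, Gstt and Ms4a among them) are uncertain.

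Each array was turned to treated over untreated, the 2 orientations with one set number were averaged, and the 3 resulting values were tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. This average joins arrays by the set number in the labels, on which the p-values rest, and counts a set once whether or not its arrays share RNA extracts. Dye effects came from a 6-array model with treatment and dye. Figures and tables were made with Python 3.11.15. After turning, arrays of one orientation correlated at 0.771 to 0.839 across probes and arrays of opposite orientation at 0.622 to 0.852, where probes are not independent replicates. No array pair held identical values.

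Before the data were examined, 28 gene lists with 840 different genes were fixed, of which 707 were on the array and 628 were measured on all 6 arrays. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01) with adjustment over the lists; 17 of 28 were called, 14 up and 3 down. With a correlation estimated from the 3 sets, 0 lists passed adjustment and 5 had an unadjusted p under 0.05. The estimate rests on few residual degrees of freedom, and so does the test that uses it. Chemokines and MHC class I genes lost their calls there although their estimates (-0.00559 and -0.0776) lay below the preset 0.01. A lost call there thus does not by itself show that correlation between members removed it. Counts of changed members are over all genes tested, with those adjusted over the list alone beside them.

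Named genes were chosen by a rule fixed in advance. It takes the 12 largest rises and 12 largest falls among changed genes with one sign on all 6 arrays, from each list the 2 members that rose most and the 2 that fell most, and 12 genes fixed by name (Nos2, Tnf, Il1b, Il6, Ptgs2, Cxcl10, Ccl5, Cd14, Tlr4, Arg1, Actb and Gapdh). A few others are named as the members of a list that did not pass or as features chosen after their values were seen, among them Ifnb1, Ccl4, Irf1, Cxcl1, Csf1, Casp1, Tfrc and Ifi202b.

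The fit was tested on simulated data with known changes for these 9607 genes. It recovered 43.8% of changes of log2 0.5, 88.8% of log2 1 and 97.5% of log2 2, and 1.36% of its calls were false. In the same data 17.4% of the calls of a fit that took the 6 arrays as separate replicates were false. The simulation gave the 2 arrays of every set a shared deviation, so an excess of false calls in that fit was fixed in advance. The real arrays showed such a deviation clearly only in set 3. The simulation also left 9407 of the genes unchanged, so its rates need not hold for these data. Of the 28 lists, 2 were moved in the simulation and both were recovered, with 0 false lists. Genes were drawn independently of each other there, so false calls from correlated members could not be seen.

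Alternatives covered the set number as a block, centring, scaling and quantile normalization of the arrays, each dye orientation alone, robust moderation, other treatments of probes and missing values, a test against a fold of 1.5, a rank-based and an estimated-correlation list test, and leaving out each set and each array. A further alternative left out the 25% of genes with the largest SD over the sets. Fits without 1 array took the remaining arrays as separate replicates. Keeping exact zeros as ratios, and the estimated correlation over 6 arrays, were added after seeing the data.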

Results

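RAW 264.7 cells, a mouse cell line that resembles macrophages, were compared after 16 hours with and without bacterial lipopolysaccharide (LPS, 100 ng/ml) given together with LPS-binding protein (100 pM), the serum protein that hands LPS to its receptor complex. The comparison asks how gene expression differs between treated and untreated cells at that time. Total RNA of treated and untreated cells was hybridised together on 6 dual-colour microarrays of 16281 probes. On 3 arrays the treated RNA carried Cy5 and on 3 it carried Cy3, and each orientation held sets numbered 1 to 3. The labels do not state that the sets came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Array number limits the precision, and signal over background is not given in the values used here.

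The direction of the value table is unstated. It was taken as Cy5 over Cy3, which is likely because the labels call the Cy5 RNA the test and the Cy3 RNA the control in both orientations. The orientations had opposite signs over all probes (r from -0.852 to -0.622), so the table was not already turned, and Il6, Il1b and Ptgs2, known LPS-induced genes, came out higher in treated cells with this direction. Ratios below are treated over untreated, with the SD over the 3 sets (n = 3), each set being the mean of its 2 orientations. Adjusted p-values are from limma.

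In cells given LPS with its binding protein, 11 of 14 inflammatory cytokine genes and 43 of 43 interferon-stimulated genes rose, and 40 of 62 cell cycle genes fell. These lists were called in limma's camera test with a preset correlation, but not with an estimated one (adjusted p = 0.271, 0.248 and 0.371). The latter test rests on few residual degrees of freedom. By the mean of a gene's probes the cytokine Il6 rose most, at 34.4-fold (log2 5.11 ± 0.47, adjusted p = 3.38e-06). The chemokine Ccl2, which attracts monocytes, rose 25.8-fold (log2 4.69 ± 0.24, adjusted p = 1.49e-06), and Il1b rose 24.7-fold (log2 4.63 ± 0.55, adjusted p = 8.4e-06). The largest fall was that of Selenbp2, a selenium-binding protein, which was 7.66-fold lower (log2 -2.94 ± 0.47, adjusted p = 3.45e-05).

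Of 9607 genes with a ratio on all 6 arrays, 3018 (31.4%) changed at an adjusted p under 0.05 in limma, 1618 of them up and 1400 down. At least 2-fold changes were seen in 353 genes that rose and 75 that fell. At least 8-fold changes numbered 47 up and 0 down. One sign on all 6 arrays was seen in 3418 of the 9607 genes, 2731 of them among the changed genes; chance would give 3.12% of all genes if the 6 arrays were independent, which those of set 3 may not be. Tested against a fold of 1.5, 450 genes passed, 366 up and 84 down. At the probe level, 4129 of 13418 probes changed, 2263 up and 1866 down, and 489 of these lacked a single gene symbol.

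Besides Il6, Ccl2 and Il1b, the 12 largest rises were those of Urah (log2 4.65), an enzyme of urate breakdown, the acute-phase gene Saa3 (4.57), the glutathione transferase Gstt4 (4.44), the cytokine Il1a (4.42), the granulocyte growth factor Csf3 (4.41), the antiviral gene Rsad2 (4.38), the interleukin 1 receptor antagonist Il1rn (4.37), the prostaglandin synthase Ptgs2 (4.26) and Slfn4 (4.13). The highest adjusted p among these was that of Urah, at 9.16e-06. Ratios in the table ended at 100-fold, and single probes of Il1b and Urah stood at that limit on 1 array, so their values are lower bounds there. The highest single probes were 2 of Ifi202b, an interferon-induced gene named here after its values were seen, at log2 5.88 and 5.85 with 1 array each at the limit; its other probe was at -0.05 (adjusted p = 0.71), and the gene's mean was 3.89. After Selenbp2, the largest falls were in Cav2 (log2 -2.39), a caveolin, Cytip (-2.32), which binds cytohesins, and Cldn11 (-1.97), a tight junction protein. Hmgn3 (-1.93), Adcyap1 (-1.82), the lysosomal sulfatase Arsb (-1.78), Sfpq (-1.70), Ccnb2 (-1.63), Racgap1 (-1.62), Cenpf (-1.60) and Id2 (-1.58) followed. Sfpq, a splicing factor, varied most among these (SD 0.74, adjusted p = 0.00231), and robust variance moderation ended its call (adjusted p = 0.0641).

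**Figure D1:**
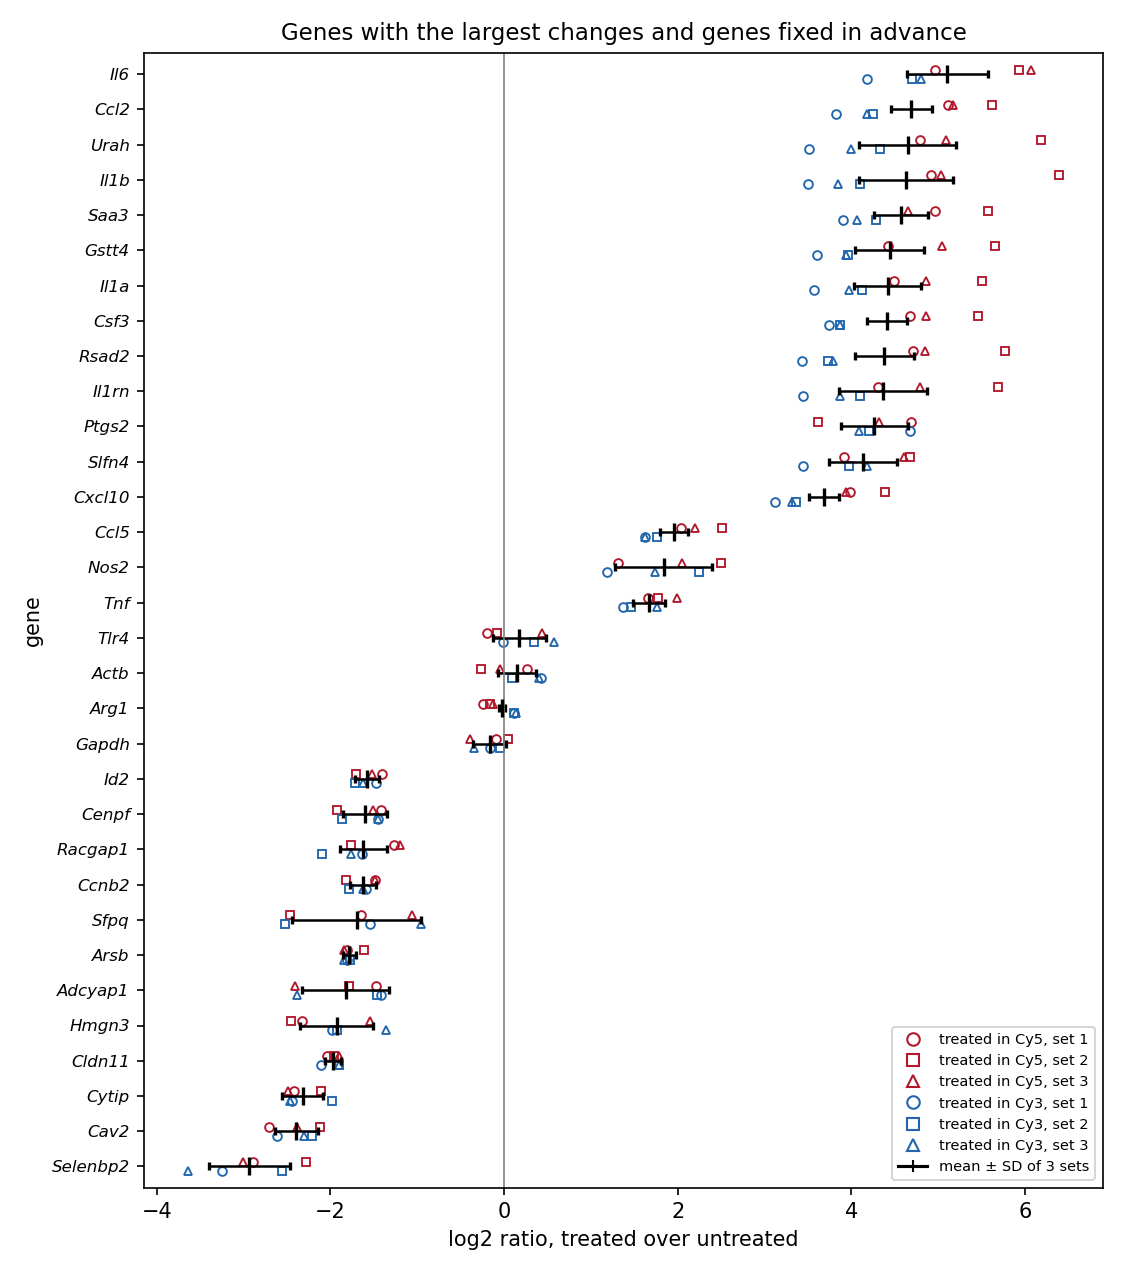
Log2 ratio of treated over untreated cells (x axis) for the 12 genes with the largest rises, the 12 with the largest falls and the genes fixed in advance (y axis). Symbols are single arrays, in red with treated RNA in Cy5 and in blue with treated RNA in Cy3, and black bars are the mean ± SD of 3 sets; Il6 at 5.11 and Selenbp2 at -2.94 mark the ends, with Actb at 0.15 and Gapdh at -0.17 near 0.

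Cytokine genes rose together. Of 14 measured members of the inflammatory cytokine list, 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 2.52-fold. Tnf, a central inflammatory cytokine, rose 3.18-fold (log2 1.67 ± 0.19, adjusted p = 3.01e-05), and Ifnb1, encoding interferon beta, rose 8.39-fold (log2 3.07 ± 0.81, adjusted p = 0.000247). The members that did not pass were Il23a (0.15), Il12a (0.07) and Csf1 (-0.11). The list's adjusted p was 5.18e-09 in limma's camera test with a preset correlation, and adjusted p = 0.271 with an estimated correlation.

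Chemokines gave 9 of 15 members up and 0 down (10 and 0 adjusted over the list alone), with a camera adjusted p of 1.18e-07 and adjusted p = 0.248 with an estimated correlation. Cxcl10, an interferon-induced chemokine, rose 12.8-fold (log2 3.68 ± 0.17) and Ccl4 rose 10.2-fold (log2 3.35 ± 0.20). Ccl5 rose 3.88-fold (log2 1.96 ± 0.16, adjusted p = 1.21e-05), but its 2 probes disagreed, at 3.66 and 0.25. Cxcl1 was at -0.02 (adjusted p = 0.863). The 2 probes of Ccl2 stood at 5.29 and 4.10. Among chemokine probes, 43.2% had an exact 0 on at least 1 array, against 15.3% of all named probes. Ccl3, Cxcl2 and Ccl17 had no probe with a ratio on all 6 arrays and were left out.

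Interferon-stimulated genes rose without exception among the 43 measured (43 and 0 adjusted over the list alone), with a median of 4.12-fold. Rsad2 (log2 4.38 ± 0.34) and Slfn4 (4.13 ± 0.39) led, and Irf1, an interferon-regulated transcription factor, had the smallest rise (0.52 ± 0.19). In the camera test the adjusted p was 1.38e-32, and adjusted p = 0.248 with an estimated correlation. Probes of the Slfn, Ifit and Ifi200 families can bind near-identical copies, so which member of such a family rose is uncertain.

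NF-kappaB and feedback regulators rose in 25 of 27 cases and fell in 0 (25 and 0 adjusted over the list alone), with a median of 2.08-fold. Il1rn was followed by Zfp36 (log2 2.81 ± 0.24), which destabilises cytokine mRNA. Rela (-0.12) and Socs3 (0.08) did not pass. Camera gave the list an adjusted p of 5.91e-17, and adjusted p = 0.248 with an estimated correlation.

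Members of the Toll-like receptor pathway went both ways, with 11 of 24 up and 3 down (11 and 3 adjusted over the list alone). Tlr1, a partner of Tlr2, rose 3.88-fold (log2 1.96 ± 0.24), and Tlr3, a receptor of double-stranded RNA, rose 3.27-fold (1.71 ± 0.71; 2.52 in set 3, 1.40 and 1.21 in sets 1 and 2). The signalling kinase Irak1 (-0.39 ± 0.01) and the adaptor Tirap (-0.36 ± 0.08) fell. Tlr4, the LPS receptor itself, was at 0.18 ± 0.31 (adjusted p = 0.332). Cd14, its co-receptor, had no ratio on 1 array and was at -0.04 ± 0.03 over the 2 complete sets (adjusted p = 0.826). The list's camera adjusted p was 0.00876, and adjusted p = 0.271 with an estimated correlation. Tlr3 lost its call under robust variance moderation (adjusted p = 0.0544). Without set 1, Tirap lost its call (adjusted p = 0.0654) and 7 members rose and 1 fell.

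Among nitric oxide and phagocyte oxidase genes, 8 of 13 rose and 1 fell (8 and 1 adjusted over the list alone). Nos2, which makes nitric oxide in activated macrophages, rose 3.57-fold (log2 1.84 ± 0.56, adjusted p = 0.00054), and Gch1, which supplies its cofactor, rose 3.01-fold (1.59 ± 0.07). Sod1 fell to 0.825 of the untreated level (-0.28 ± 0.13, adjusted p = 0.0366), a call lost without set 1, 2 or 3 (adjusted p = 0.0693, 0.0955 and 0.153), which left 0 members down. Arg1, an arginase of alternatively activated macrophages, was at -0.03 ± 0.03 (adjusted p = 0.822), with opposite signs in the 2 dye orientations. The list had a camera adjusted p of 0.000698, and adjusted p = 0.281 with an estimated correlation.

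**Figure D2:**
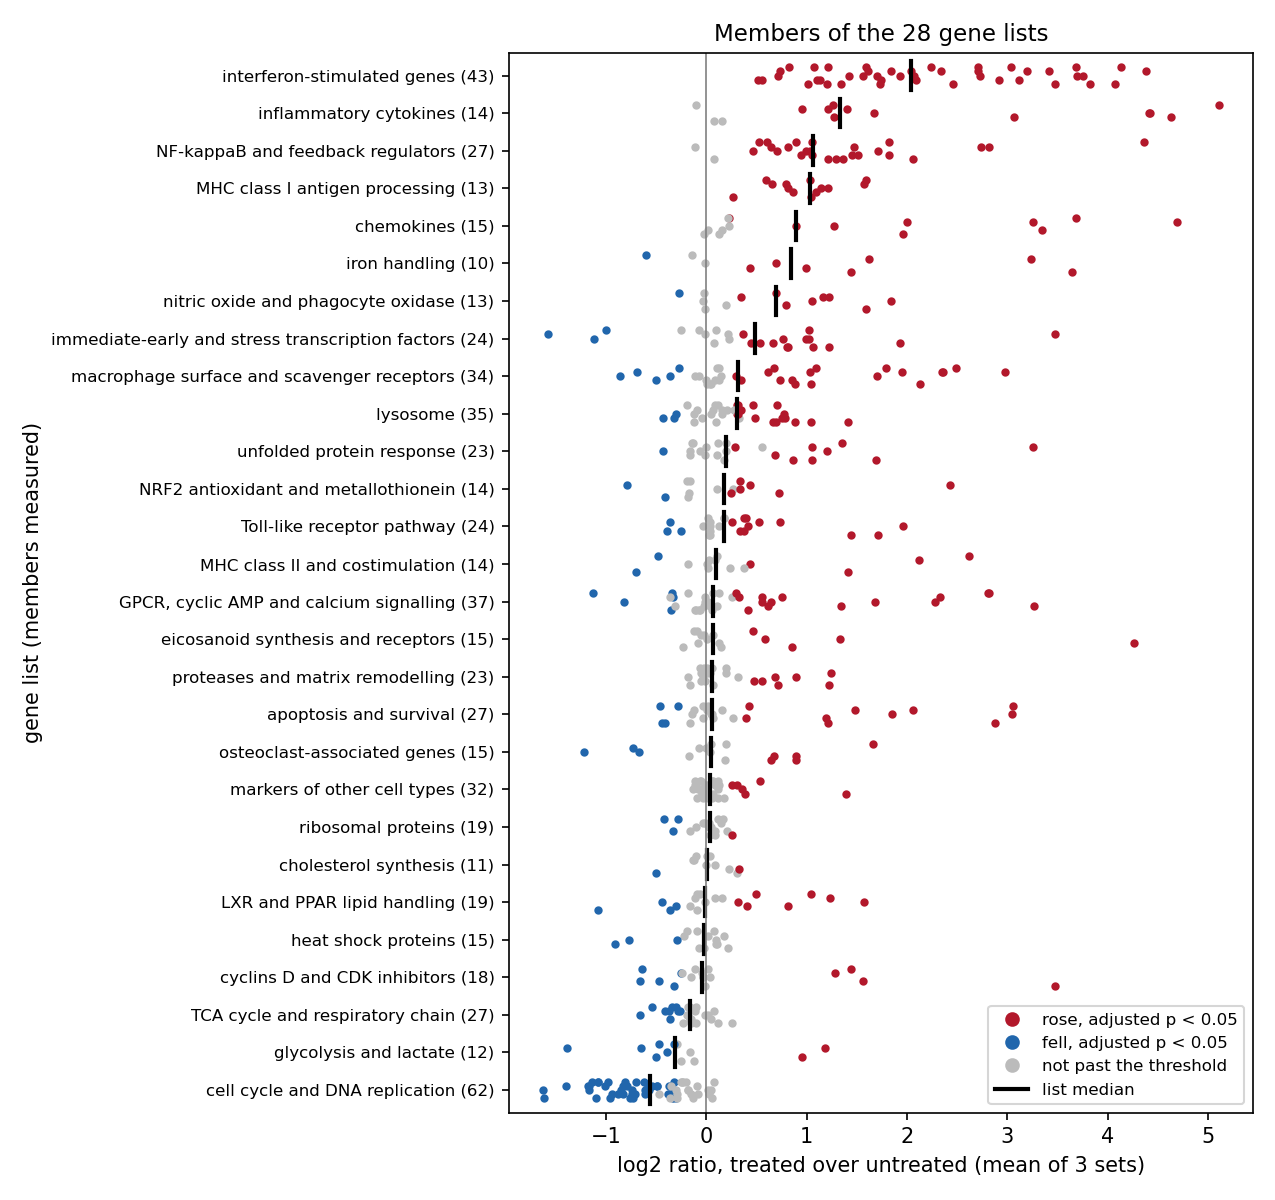
Log2 ratio of treated over untreated cells (x axis) for each measured member of the 28 gene lists (y axis, with the number measured), as the mean of 3 sets. Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and black lines are list medians, from 2.04 for interferon-stimulated genes to -0.558 for the cell cycle list.

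Genes that process antigen for MHC class I rose in 13 of 13 cases (13 and 0 adjusted over the list alone), with a median of 2.04-fold. The peptide transporter Tap1 (log2 1.59 ± 0.09) and H2-T23 (1.57 ± 0.06), whose probe may bind related H2 genes, led. This list had a camera adjusted p of 4.92e-10, and adjusted p = 0.248 with an estimated correlation. MHC class II and costimulation genes split, with 4 of 14 up and 2 down (5 and 2 adjusted over the list alone) and no call of the list (adjusted p = 0.0904). The checkpoint ligand Cd274 (2.62 ± 0.16) and the costimulatory receptor Cd40 (2.11 ± 0.10) rose, while H2-DMa (-0.70 ± 0.09) and H2-Eb1 (-0.48 ± 0.22) fell. Without set 3 this list was called up (adjusted p = 0.0349).

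Macrophage surface and scavenger receptors rose in 18 of 34 cases and fell in 5 (18 and 5 adjusted over the list alone). The receptor kinase Axl rose 7.84-fold (log2 2.97 ± 0.20) and the inhibitory Fc receptor Fcgr2b 5.63-fold (2.49 ± 0.28). Trem2 (-0.86 ± 0.10) and Fcgr3 (-0.69 ± 0.16) fell. For these receptors the camera adjusted p was 5.5e-05, and adjusted p = 0.248 with an estimated correlation. Lysosomal genes gave 17 of 35 up and 3 down (20 and 3 adjusted over the list alone). The sterol carrier Npc2 (1.41 ± 0.18) and the protease Ctsc (1.04 ± 0.10) rose, and Ctsb (-0.44 ± 0.18) and Tfeb (-0.33 ± 0.05) fell. Their camera adjusted p was 0.000368, and adjusted p = 0.324 with an estimated correlation. Tfeb lost its call without set 1 (adjusted p = 0.063), where 12 lysosomal genes rose and 1 fell, and 11 rose without set 2.

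Cell cycle and DNA replication genes fell. Of 62 measured members, 40 fell and 0 rose (47 and 0 adjusted over the list alone), and the median was 1.47-fold lower. Ccnb2, a mitotic cyclin, was 3.09-fold lower (log2 -1.63 ± 0.15, adjusted p = 2.39e-05), and Racgap1, needed for cytokinesis, 3.08-fold lower (-1.62 ± 0.27). Cenpf, a kinetochore protein outside the list, was 3.04-fold lower (-1.60 ± 0.26). The list had a camera adjusted p of 2.02e-15, and adjusted p = 0.371 with an estimated correlation; that correlation came to 0.704. Without set 1, 2 or 3, 36, 34 and 52 members fell.

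Among D cyclins, cyclin-dependent kinase inhibitors and linked regulators, 4 of 18 rose and 5 fell (4 and 5 adjusted over the list alone), with no call of the list (adjusted p = 0.803). Myc, a growth-promoting transcription factor, rose 11.1-fold (log2 3.47 ± 0.46, adjusted p = 1.5e-05), and Mxd1, its antagonist, rose 2.95-fold (1.56 ± 0.35). Ccnd3 (-0.67 ± 0.05) and the antiproliferative gene Btg2 (-0.64 ± 0.26) fell. The list's median was -0.04 and tested down, while its mean was 0.27. Without set 1, 3 members fell.

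Of the 25 genes on the glycolysis and lactate list, 12 were measured, of which 6 fell and 2 rose (6 and 2 adjusted over the list alone). Aldoa, Pgk1, Pgam1, Pkm, Slc2a1 and Hk1 had no probe with a ratio on all 6 arrays. Eno1 and Tpi1 were not found on the array, so much of the pathway itself was not measured. The oxygen-sensing hydroxylase Egln3 (log2 -1.39 ± 0.18) and the lactate transporter Slc16a3 (-0.65 ± 0.21) fell. Pfkfb3 (1.18 ± 0.32), which promotes glycolysis, and Hif1a (0.95 ± 0.74), an oxygen-regulated transcription factor, rose. Of the probes of this list, 50% had an exact 0 on at least 1 array. Its camera adjusted p was 0.016, and adjusted p = 0.281 with an estimated correlation. The call was lost without set 3 (adjusted p = 0.0584) and with exact zeros kept as ratios, an alternative chosen after seeing the data (0.141). Hif1a stood at 1.81 in set 3 and at 0.53 in sets 1 and 2, its value without set 3 was 0.53, and its call ended under robust moderation (adjusted p = 0.187).

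Genes of the citric acid cycle and respiratory chain fell in 9 of 27 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of 1.12-fold lower. Sucla2 (log2 -0.66 ± 0.10) and Cox7a2 (-0.54 ± 0.05) fell most. With camera the adjusted p was 0.00104, and adjusted p = 0.323 with an estimated correlation. Without set 1 and without set 2, 5 members fell. Iron handling genes rose in 7 of 10 cases and fell in 1 (7 and 1 adjusted over the list alone). Lcn2, which binds bacterial siderophores, rose 12.5-fold (3.64 ± 0.10), ceruloplasmin (Cp) rose 9.41-fold, and Pcbp1 fell (-0.60 ± 0.21). Tfrc, the transferrin receptor, was at 2.54 in set 3 against 0.98 and 0.81 in sets 1 and 2, as seen afterwards. Their camera adjusted p was 0.00298, and adjusted p = 0.271 with an estimated correlation.

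Lipid and redox genes changed singly, and none of their 3 lists was called. In LXR and PPAR lipid handling, 7 of 19 rose and 4 fell (7 and 4 adjusted over the list alone, list adjusted p = 0.537), among them Fabp4 (log2 1.57 ± 0.39), Lpl (1.23 ± 0.83), Fasn (-1.08 ± 0.27) and Scd1 (-0.45 ± 0.23). That list's median was -0.02, while its mean was 0.18 and it tested up. The 2 probes of Fabp4 disagreed, at 2.87 and 0.28 (adjusted p = 0.173). Lpl was at 2.19 in set 3 against 0.74 and 0.76 in sets 1 and 2, its value without set 3 was 0.75, and robust moderation ended its call (adjusted p = 0.156). In cholesterol synthesis, Sc5d (0.32 ± 0.10) rose and Sqle (-0.50 ± 0.20) fell out of 11 (1 and 1 adjusted over the list alone, list adjusted p = 0.992, tested down with a median and a mean of 0.01). In the NRF2 antioxidant list, 6 of 14 rose and 2 fell (7 and 2 adjusted over the list alone, list adjusted p = 0.384), with the cystine transporter Slc7a11 (2.42 ± 0.33) and Mt2 (0.72 ± 0.20) up and Gclc (-0.79 ± 0.14) and Gsr (-0.42 ± 0.22) down. Sc5d and Scd1 lost their calls without set 1 (adjusted p = 0.0646 and 0.0831), Sc5d also without set 3 (0.0567), and Gsr without set 2 (0.0724). Without set 1, 2 lipid handling genes fell, and 3 NRF2 genes rose without set 1 and without set 2.

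Unfolded protein response genes rose in 9 of 23 cases and fell in 1 (9 and 1 adjusted over the list alone). The stress transcription factor Ddit3 rose 9.53-fold (log2 3.25 ± 0.22) and Chac1 3.22-fold (1.69 ± 0.09), while Xbp1 fell (-0.43 ± 0.13). These genes had a camera adjusted p of 0.00497, and adjusted p = 0.371 with an estimated correlation. The call was lost on the arrays with treated RNA in Cy5 alone (adjusted p = 0.0553), and the median of 0.20 was 0.05 without set 1 and 0.30 without set 2. Of 15 heat shock genes, 3 fell and 0 rose (2 and 0 adjusted over the list alone, list adjusted p = 0.434), led by the co-chaperones Dnajb1 (-0.91 ± 0.17) and Dnaja1 (-0.77 ± 0.45). Their median of -0.03 was 0.00324 after quantile normalization and 0.0347 without set 3.

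Apoptosis and survival genes rose in 10 of 27 cases and fell in 4 (11 and 4 adjusted over the list alone). The antiapoptotic genes Bcl2a1a (log2 3.06 ± 0.09) and Bcl2a1d (3.04 ± 0.15) rose, though their near-identical copies leave open which of them did. The proapoptotic Bid (-0.46 ± 0.12) and Ripk3 (-0.45 ± 0.22), a kinase of necroptosis, fell. The inflammasome protease Casp1 rose (2.05 ± 1.28), at 3.54 in set 3 against 1.28 and 1.34 in sets 1 and 2. Camera gave an adjusted p of 0.0236, and adjusted p = 0.323 with an estimated correlation. This call was lost with a rank-based test (adjusted p = 0.0975), and the median of 0.06 was -0.000692 without set 1 and 0.12 without set 2. Without set 2, Ripk3 lost its call (adjusted p = 0.0512) and 2 members fell.

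Immediate-early and stress transcription factors rose in 14 of 24 cases and fell in 3 (15 and 4 adjusted over the list alone). Myc and Cebpd (log2 1.93 ± 0.17), a factor of the acute-phase response, rose, and Id2 (-1.58 ± 0.14) and Klf2 (-1.11 ± 0.12) fell. For this list camera gave an adjusted p of 0.000698, and adjusted p = 0.271 with an estimated correlation. In G protein and calcium signalling, 15 of 37 rose and 5 fell (15 and 5 adjusted over the list alone), with no call of the list (adjusted p = 0.051). The G protein regulators Rgs16 (3.26 ± 0.27) and Rgs1 (2.81 ± 1.25) rose, and Prkar1a (-1.13 ± 0.15) and Rgs14 (-0.82 ± 0.15) fell. The list was called up without set 1 (adjusted p = 0.0239), without set 3 (0.0124) and with treated RNA in Cy5 alone (0.0419). Rgs1 stood at 4.26 in set 3 against 2.13 and 2.06, and robust moderation ended its call (adjusted p = 0.0844).

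Eicosanoid genes gave 5 of 15 up and 0 down (5 and 0 adjusted over the list alone), with Ptgs2 and the prostaglandin receptor Ptger2 (log2 1.33 ± 0.40) leading and no call of the list (adjusted p = 0.0853). It was called without set 1 (adjusted p = 0.0332), and without set 3, 1 member fell. Proteases and matrix genes gave 7 of 23 up and 0 down (7 and 0 adjusted over the list alone), led by Adam8 (1.24 ± 0.15) and the protease inhibitor Timp1 (1.22 ± 0.15). Their camera adjusted p was 0.0302, and adjusted p = 0.281 with an estimated correlation. That call was lost with treated RNA in Cy5 alone (adjusted p = 0.0537), and the median of 0.06 was 0.12 without set 2. Osteoclast-associated genes split, with 5 of 15 up and 3 down (6 and 3 adjusted over the list alone, list adjusted p = 0.367). The phosphatase Acp5 (1.67 ± 0.24) and Mitf (0.89 ± 0.40) rose, and Ocstamp (-1.22 ± 0.14), needed for osteoclast fusion, and Nfatc1 (-0.73 ± 0.08) fell.

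Markers of other cell types gave 6 of 32 up and 0 down (3 and 0 adjusted over the list alone), with no call of the list (adjusted p = 0.308). The matrix proteoglycans Lum (log2 1.39 ± 0.39) and Dcn (0.54 ± 0.44, adjusted p = 0.0366) led, while Dcn lost its call without set 2 (adjusted p = 0.142) and was at 0.35 without set 3. Ribosomal protein genes gave 1 of 19 up and 3 down (0 and 3 adjusted over the list alone, list adjusted p = 0.992, tested down with a median of 0.03 and a mean of -0.01). Of their probes, 56.8% had an exact 0 on at least 1 array. Rps20 (-0.42 ± 0.13) and Rpl14 (-0.33 ± 0.18) fell and Rplp1 rose (0.26 ± 0.14), and Rplp1 and Rpl14 lost their calls without set 2 (adjusted p = 0.211 and 0.0854), Rplp1 also without set 1 (0.168) and Rpl14 without set 3 (0.0996). Without set 2 and without set 3, 1 member fell. Actb was at 0.15 ± 0.22 (adjusted p = 0.327) and Gapdh at -0.17 ± 0.19 over 10 probes (adjusted p = 0.224).

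Set 3 stood apart from sets 1 and 2. In a fit with a term for set, 140 genes differed between sets, and 136 of these were highest in set 3. Fam111a was at 2.95 in set 3 against -0.24 and -0.53 in sets 1 and 2, and Sh3bgrl at 3.10 against 0.19 and 0.37. These genes and Casp1 were singled out after their values were seen. Without set 3, 2990 genes changed, of which 2665 were among the 3018, and the cell cycle list had 52 members down in place of 40.

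Ratios depended on the dye for the largest rises. The 47 genes that rose at least 8-fold had a median log2 ratio of 3.94 with treated RNA in Cy5 and 3.27 in Cy3, while the 75 that fell at least 2-fold had -1.23 in both. In a model with treatment and dye, 45 of 13418 probes had a dye effect, 5 toward Cy5 and 40 toward Cy3 (limma, adjusted p under 0.05). Without set 1, 2 or 3 this number was 20, 14 and 23, with 0 toward Cy5 each time. Averaging the orientations removes a dye effect that is equal in both. The SD over sets therefore leaves out the gap between orientations. For Il1b that gap was 5.44 with treated RNA in Cy5 against 3.81 in Cy3, not called as a dye effect (limma, adjusted p = 0.141).

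**Figure D3:**
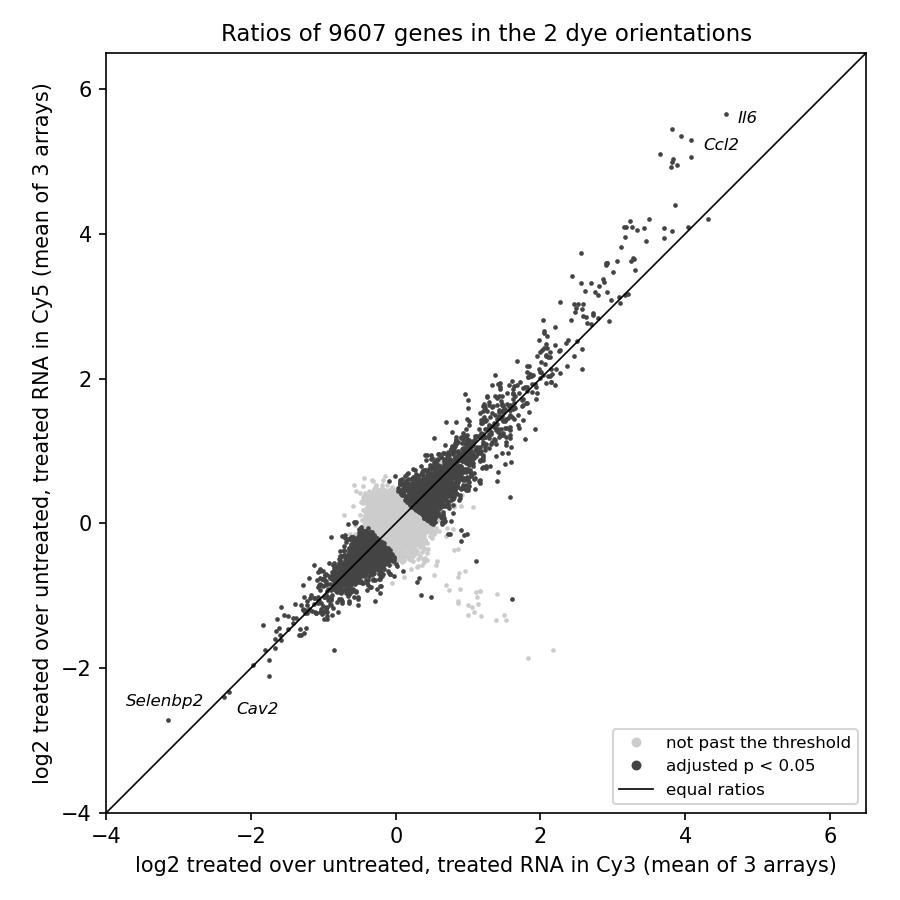
Mean log2 ratio of treated over untreated cells on the 3 arrays with treated RNA in Cy5 (y axis) against the 3 with treated RNA in Cy3 (x axis), 1 point per gene for 9607 genes. Dark points changed at an adjusted p under 0.05 and the line marks equal ratios; of the 47 genes that rose at least 8-fold, 91.5% lie above it, such as Il6 and Ccl2, with Ptgs2 slightly below, while Cav2 and Selenbp2 lie near or slightly above it at the low end.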

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

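The tests of exact zeros in bright spots, of both explanations for the dye orientations and of both explanations for set 3 were chosen only after the result was seen.

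Ccl2 differed between the dye orientations, with a log2 ratio 1.22 larger when treated RNA carried Cy5 than when it carried Cy3 (limma, adjusted p = 0.0409). Of the 28 lists, 4 differed in a test of that difference over lists (camera with a preset correlation). The median over members of each gene's ratio with treated RNA in Cy5 minus that in Cy3 was 0.257 for chemokines (adjusted p = 0.0061), 0.105 for interferon-stimulated genes (0.0464), 0.279 for iron handling (0.0246) and -0.286 for ribosomal proteins (0.0061). These are differences within genes and not between list medians, which for interferon-stimulated genes were 1.95 with treated RNA in Cy5 and 2.05 in Cy3.

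The dependence of large rises on the dye may come from the measurement. The 47 genes that rose at least 8-fold had a median difference of 0.656 (95% bootstrap interval 0.461 to 0.719), and 91.5% of them were larger with treated RNA in Cy5. Ratios stretched in proportion on those arrays, by the factor of 1.2 seen in these genes, would give -0.229 in the 75 genes that fell at least 2-fold. The value there was -0.0169 (interval -0.0598 to 0.0208), with -0.00575, -0.0375 and -0.0257 in sets 1, 2 and 3. This argues against a uniform stretch. Both intervals resampled genes and not arrays, so they leave out variation between arrays. A higher signal floor in the Cy5 channel would shrink strong rises when the untreated RNA carries Cy5. The 306 genes that rose 2- to 8-fold differed by a median of 0.0579, less than the 0.656 of the strongest rises, which such a floor would give. This explanation stays open, because 0 genes fell at least 8-fold and its counterpart in falls could not be read. No biological explanation was tested.

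Exact zeros were not spread evenly over genes. Of ribosomal protein probes, 56.8% had an exact 0 on at least 1 array, against 20.4% of probes for markers of other cell types (Fisher's exact test, two-sided, p = 0.000516). The share was 50% for glycolysis probes and 43.2% for chemokine probes, against 15.3% of all named probes. Spots too bright for a ratio are a candidate explanation, since ribosomal mRNA is abundant. Spots too dim for a ratio cannot be told apart from other causes, because the 20.4% of probes for other cell types were not detectably above the 15.1% of other named probes (odds ratio 1.44, 95% interval 0.639 to 2.94; Fisher's exact test, two-sided, p = 0.316). No biological explanation was tested.

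Set 3 stood apart in both of its arrays. Genes chosen on 1 of its arrays, as over 1 above sets 1 and 2, lay above them on the other array as well, by a median of 1.23 for one choice and 1.41 for the other, which argues against an artefact of a single array. A proportionally stronger response was read in the 419 genes called at least 2-fold without set 3. Set 3 was there at a median of 0.993 times sets 1 and 2, so those genes showed none. The 95% bootstrap interval, 0.975 to 1.01, resampled genes and leaves out variation between arrays. The 419 genes were chosen on sets 1 and 2 alone, which can lower this factor. It puts none of the genes chosen on set 3 over 0.0511 above sets 1 and 2. Those genes lay near 0 in sets 1 and 2 (medians 0.00422 and -0.118), where a factor predicts little, so they could not test this explanation. Of 123 genes over 1 above on both arrays, 28 were among the genes changed by treatment. A difference in the RNA or culture pair used for set 3 stays open, and whether it is technical or biological was not tested.

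Joined by the labels' numbering, 140 genes differed between sets. Of the 6 ways of joining the arrays of one orientation to those of the other, the next highest gave 119 and also kept set 3 joined, and the others gave 0, which is consistent with a shared RNA pair in set 3 and leaves sets 1 and 2 undecided.

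Other splits of the 6 arrays into 3 and 3 were counted with the 6-array model. The real split by dye orientation called 3649 genes and the highest other split 2, and 4895 probes against 0, so 1 of 10 splits was as large in each case. With 10 splits no share under 0.05 can be reached. Every other split also mixes the orientations, so the treatment effect enters its residual spread. The low counts of those splits were thus largely fixed in advance.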

How the results depend on the processing

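The count of changed genes stayed within 1.5 times of 3018 under 23 alternatives and fell to 450 when tested against a 1.5-fold change. Among the 23, fits without 1 array took arrays as separate replicates, and their 3064 to 3463 genes belong beside that fit's 3649. Another left out the 25% most variable genes (3114 of 7205 changed) and so selected on the spread that the test itself uses. Leaving out 1 set gave 2158 to 2990 genes. Changed probes fell to 2159 with exact zeros kept as ratios of 0 (chosen after seeing the data), where 16281 probes were tested. Probes with a dye effect numbered 3 with the set number as a fixed replicate block and 14 to 23 without 1 set; their cause was not tested. The number of lists called was 15 to 19 otherwise, but 0 with an estimated correlation over 3 sets (lowest adjusted p 0.248) and 0 over 6 arrays (0.0503, chosen after seeing the data; 10 lists had an unadjusted p under 0.05). Arg1 turned to 0.12 on the arrays with treated RNA in Cy3 and Actb to -0.0153 on those with treated RNA in Cy5, neither past the threshold. Of single-gene values under the alternatives, 2292 kept direction and side of the threshold, 95 lost the threshold, 2 gained it and 2 turned; of list medians, 250, 41, 5 and 12 did. Lists whose median turned had reported medians between -0.0403 and 0.0568. With treated RNA in Cy5 alone, lipid handling was at 0.0449, osteoclast-associated genes at -0.046 and ribosomal proteins at -0.0704. Without 1 set, medians ran from -0.0905 to 0.00817 for D cyclins and kinase inhibitors, -0.0349 to 0.105 for cholesterol synthesis, -0.0435 to 0.0352 for lipid handling, -0.0507 to 0.0347 for heat shock, -0.000692 to 0.116 for apoptosis and -0.0193 to 0.107 for ribosomal proteins; the cause was not tested. Centring, scaling or quantile normalization moved the median of all genes by at most 0.00613. Signal over background was not analysed here, so what it limits is unknown.

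Deviations of arrays with one set number correlated at 0.544 in set 3, 0.188 in set 1 and 0.05 in set 2, and those of differently numbered arrays of sets 1 and 2 at 0.188 and 0.196. The numbers were therefore not taken to pair the samples as a block, although the average per set joins arrays by them. By these deviations both arrays of set 3 correlated best with each other, and those of sets 1 and 2 did not. The deviations are from a mean of 3 arrays, so a departure of set 3 moves sets 1 and 2 alike. They therefore cannot show that sets 1 and 2 are unpaired. Among turned ratios of opposite orientations, the arrays of set 1 correlated best with each other (0.778) and those of set 2 did not (0.622). The set number as a fixed replicate block gave 4265 genes, as a random replicate block 3088, and no replicate block 3649, with 2918, 2866 and 2994 shared with the 3018. With the fixed block, Gapdh and Tlr4 passed the threshold (adjusted p = 0.0217 and 0.0409), and the apoptosis and protease lists did not (0.0668 and 0.0594).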

Other observations

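The tests of neighbouring genes were chosen only after the result was seen, as were the genes named for them.

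Gstt4 (log2 4.44 ± 0.40), Gstt1 (3.63 ± 0.49), Gstt3 (1.66 ± 0.31) and Ddt (2.33 ± 0.26), which follow each other in the reference gene order, rose on all 6 arrays. Gstt2, on the other side of Gstt4, rose by less (0.65 ± 0.03), and Mif beyond it was at -0.07 ± 0.08 (limma, adjusted p = 0.557). Ddt encodes a relative of the cytokine Mif, and the Gstt genes encode theta-class glutathione transferases. In the Ms4a cluster of membrane proteins, Ms4a6c (3.47 ± 0.15), Ms4a6d (3.44 ± 0.10) and Ms4a4c (2.74 ± 0.30) rose, while Ms4a7 (0.04 ± 0.06, adjusted p = 0.722) and Ms4a2 (0.04 ± 0.12, adjusted p = 0.792) did not pass. Probes within the Gstt and Ms4a families could bind each other's transcripts, which was not tested, and Ddt lies outside both families.

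A chance placement of the genes that rose was tested on neighbours whose symbols differ in their first 3 letters, which leaves out most family members. Among 8569 such pairs of adjacent measured genes, 22 held 2 genes that both rose at least 2-fold, among them Ddt with Gstt3, which prompted the test, and pairs in the clusters of immunity-related GTPases around Igtp and Irgm1. Without 6 genes on each side of Gstt4, Ms4a6c, Igtp and Irgm1, 17 of 8548 pairs remained, such as Rsad2 with Cmpk2, Tap1 with Psmb8 and Nos2 with Lgals9. Shuffles of positions among the genes kept gave a mean of 10.6 (1000 shuffles, highest 22; permutation test, one-sided, p = 0.043), and shuffles among all genes a mean of 11.6 (highest 24, p = 0.0749). The outcome depends on that choice, so a chance placement stays open.

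Other genes outside the lists rose, chosen here after their values were seen. The complement factor Cfb rose 8.69-fold (log2 3.12 ± 0.18, adjusted p = 2.64e-06 in limma), the histamine-producing enzyme Hdc 8.86-fold (3.15 ± 0.15, adjusted p = 1.99e-06), the protein C receptor Procr 6.86-fold (2.78 ± 0.34, adjusted p = 1.46e-05) and the transcription factor Batf 4.78-fold (2.25 ± 0.14, adjusted p = 5.59e-06), each on 6 of 6 arrays.

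Some hypoxia-responsive genes were lower in treated cells, among them Adm (log2 -1.30 ± 0.45, adjusted p = 0.0011) and Bnip3 (-1.14 ± 0.16, adjusted p = 0.000135), while Pfkfb3 rose (1.18 ± 0.32, adjusted p = 0.000528). In a separate list of targets of hypoxia-inducible factors, without Adm, Bnip3, Egln3 and Ldha and without members of the other lists such as Pfkfb3, 11 of 25 measured members fell and 2 rose, with a median of -0.268 (camera adjusted p = 0.00328, adjusted p = 0.273 with an estimated correlation). Adjustment was over this list and that of MYC targets alone, and the unadjusted camera p was also 0.00328. Members that fell included Higd1a (-0.91) and Gbe1 (-0.87), and P4ha1 (0.46) and Pgm2 (0.35) rose. Without set 1, 2 or 3, 8, 11 and 11 members fell and 1, 1 and 2 rose.

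Myc rose while cell cycle genes fell. MYC target genes did not rise with it: of 23 measured members off the other lists, 13 fell and 1, Odc1 (log2 1.95 ± 0.25), rose, with a median of -0.368 (camera adjusted p = 0.000524, adjusted p = 0.391 with an estimated correlation). Adjustment was over this list and that of hypoxia-inducible factor targets alone, and this list too was prompted by values already seen. Without set 2, 6 members fell. The fall of the cell cycle list did not rest on 1 set, since at least 34 of its 62 members fell without any one of the sets.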
